A study of Mus musculus with 16 samples.

How the data were processed

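Spleen and thymus RNA of 4 male EMP3 mutant mice, 17 weeks old, was compared with a pool of wild-type RNA on two-colour arrays. Per the labels' protocols, 20 µg of total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5, and each mutant sample was hybridised with the reference labelled in the other dye. The channel labels list 4 wild-type mice in the pool and the design text gives the same number, while the labelling protocol speaks of 6. The series title names thymus and brain, and the sample labels name spleen and thymus; the sample labels were followed. Scanner, image software, background correction, normalization and genome build are not given in the sources used here.

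The deposited values are log ratios of the 2 channels, read here as log2 ratios, with both signs and array medians near 0. On each array 25 to 137 probes shared 1 constant of 15.1 to 16.9 in size, while the largest other value in size was 7.66. The constant was read as a placeholder for spots without signal in 1 channel and set to missing, and its size is near the range of a scanner on the log2 scale, which is the basis for the log base. Its sign was positive where the mutant RNA carried Cy5 and negative where it carried Cy3, on 16 of 16 arrays, so the ratios were taken as already turned to 1 orientation relative to the mutant channel. In this orientation the 2 arrays of a mouse correlated at 0.052 to 0.424 in spleen and at -0.922 to -0.249 in thymus. Thymus arrays of different mice, without mouse 2, correlated at -0.32 to -0.142 with opposite mutant dyes and at 0.144 to 0.393 with the same dye. Those correlations do not settle the orientation in thymus, and the placeholder does so only if the same dye lacked signal on every array. That the mutant is the numerator is likely from the design text, and no label states it. On an array 124 to 618 probes had no value. The files give no intensities, so the depth behind a value is unknown and the number of arrays and mice limits the precision.

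Thymus mouse 2 was left out because its 2 arrays held nearly mirrored values (r = -0.922, 83.8% of the probes within 0.01 of the pair's median sum, 64 placeholders in common against 1 to 15 in the other pairs), which leaves no dye exchange; which of the 2 arrays is right, if either, is unknown. This and the treatment of the placeholders were decided after the values had been seen and before any test. The mean of the 2 arrays of a mouse, where both had a value, was 1 replicate, and a probe was tested in a tissue with at least 3 mice. Log ratios were fitted with limma 3.58.1 in R 4.3.3 as 1 fit with a mean per tissue; the ratio against 0 and the difference between the tissues were tested with moderated statistics and Benjamini-Hochberg adjustment at 0.05. The mouse numbers pair the tissues because the same animals gave both. Deviations from the tissue means of the same mouse correlated at -0.052, -0.012 and -0.070 for mice 1, 3 and 4. The fit was tested on simulated data: in spleen it recovered 70 of 100 probes changed by 0.5 and 93 of 100 changed by 1 on the log2 scale, and for the difference 41 and 79 of 100, with 9.1% of the calls for the difference false. Fitted alone, spleen gave 38 and 79 of 100. A share of false calls depends on how many probes are changed, so the simulated shares do not carry over to the data. No probe was changed in the simulated thymus, so recovery there was not measured.

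The platform annotation gave 1 gene symbol to 12771 of 20794 probes and none to 8023; no probe had several. All 12771 were found by gene number in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was used for names only. Together they name 9030 genes, 2754 of them with more than 1 probe. Gene lists were fixed before the data were examined and tested with camera at its preset correlation of 0.01, and with an estimated correlation beside it, on the mean of a gene's probes, over the 8594 genes (95.2%) complete in every mouse. Counts of list members come from the same fit on gene means, in which 3379 of 8836 genes passed in spleen, 0 of 8834 in thymus and 1112 of 8787 for the difference.

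The genes named were fixed by rule before the data were examined: Emp3 and its relatives; in each tissue and direction the 12 probes with 1 gene symbol and the largest mean log2 ratio in size among those past the threshold with the same sign in all mice, filled up with the smallest p where fewer passed; of a list past the threshold the 4 members with the smallest p in its direction, and of other lists at most 2; and the 8 probes with the smallest p for the difference. The members of other lists are given for the 6 spleen lists with the smallest p, a restriction set after the list results had been seen. Emp1 and P2rx7 are named at no probe of the annotation used here.

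Agreement of the gene names with the values was checked with Spearman's rho over pairs of probes of 1 gene more than 400 IDs apart, against 1000 shuffles of the pairs. Alternatives fixed before the data were examined were array medians set to 0, quantile normalization, the other reading of the dye exchange, a fit of all arrays with a dye term and the mouse as a random block, each tissue alone, robust moderation, complete probes, a 1.2-fold test, gene means, the mouse as a block and leaving out each mouse. Alternatives chosen after seeing the data were the placeholders kept, the mirrored pair used as deposited or with either sign, a running median over 49 neighbouring IDs removed from each array, and the variance of a pool of 4 mice added.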

Results

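The data were 16 two-colour cDNA microarrays on which RNA from EMP3 mutant mice was hybridised against RNA pooled from wild-type mice of the same tissue. EMP3 is a small membrane protein of the PMP22 family. RNA came from the spleen and the thymus of 4 male mutant mice aged 17 weeks, with 8 arrays per tissue, and each mouse was hybridised on a pair of arrays with the dyes exchanged. The deposited values were log ratios for 20794 probes, and 20046 to 20639 of them were measured on an array. Array medians lay between -0.023 and 0.086. The scale was read as log2 and the direction as mutant over pool. Neither is stated in the labels: the direction is the likely one, because the design text sets the mutants against the pool. If the pool is the numerator, every higher value below is a lower one and the reverse. A further doubt is whether the sign on the Cy3 arrays had already been turned, as taken here. Under the other reading, which turns those arrays, 12 probes passed an adjusted p of 0.05 in spleen in limma, against 7577. For the difference between the tissues 0 passed, against 2692. The mean of the 2 arrays of a mouse was 1 replicate. The 2 thymus arrays of mouse 2 were near mirror images of each other (Pearson's r = -0.922 across probes). Their sum lay within 0.01 of its median for 83.8% of the probes, against 1.33% to 6.08% in the other 7 pairs, so they were not used as a pair of separate hybridisations and were left out. This gave n = 4 mice for spleen and n = 3 for thymus. Gene names are those of the platform annotation, which gave 12771 probes a single gene symbol. Different probes annotated to the same gene did not share their values in these data, as measured further on. Each gene named here therefore stands for the probe that carries its name, and each member of a gene list for the mean of its probes. Neither stands for an established transcript.

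The targeted gene was examined first. Emp3 was represented by 2 probes. In spleen, probe 4348 had a log2 ratio of 0.20 ± 0.25 (SD, n = 4) and probe 11822 one of 0.27 ± 0.38 (SD, n = 4), and neither passed the threshold in limma (adjusted p = 0.114 and 0.117). The mice did not share a direction: probe 4348 was at 0.03, 0.48, 0.36 and -0.05 in mice 1 to 4, and probe 11822 at -0.08, 0.30, 0.79 and 0.07. An exact two-sided sign-flip test over the 4 mice gave p = 0.375 for each probe and decides nothing, since 0.125 is the smallest p that 4 mice allow. Probe 4348 was at 0.47 in spleen with the mutant in Cy5 alone and at -0.06 with the mutant in Cy3 alone, values that each carry the dye effect. In thymus the ratios were -0.05 ± 0.10 (SD, n = 3) for probe 4348 and 0.05 ± 0.05 (SD, n = 3) for probe 11822, both with an adjusted p of 1 in limma, and an exact test cannot go below 0.25 with 3 mice. Without mouse 1, the thymus value of probe 4348 was 0.01. A lower Emp3 signal was not detected by limma in either tissue. The labels do not say what kind of mutation the mice carry or which part of the transcript the probes cover, so these ratios do not check the labels. Among the relatives of Emp3, the Emp2 probes 18713 and 19447 had spleen log2 ratios of 0.04 ± 0.19 and -0.16 ± 0.05 (SD, n = 4), and the Pmp22 probe, for the peripheral myelin protein that names the family, -0.16 ± 0.27 (SD, n = 4). None of them passed the threshold in limma. Of 20 tested genes that neighbour Emp3 on its chromosome, 6 were higher and 4 lower in spleen past an adjusted p of 0.05, and 11 passed when adjusted over the list alone. Over all genes, 3379 of 8836 passed in spleen. As a list the neighbours did not pass the threshold against the other genes in spleen (camera, adjusted p = 0.963) or in thymus (adjusted p = 0.878).

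**Figure D1:**
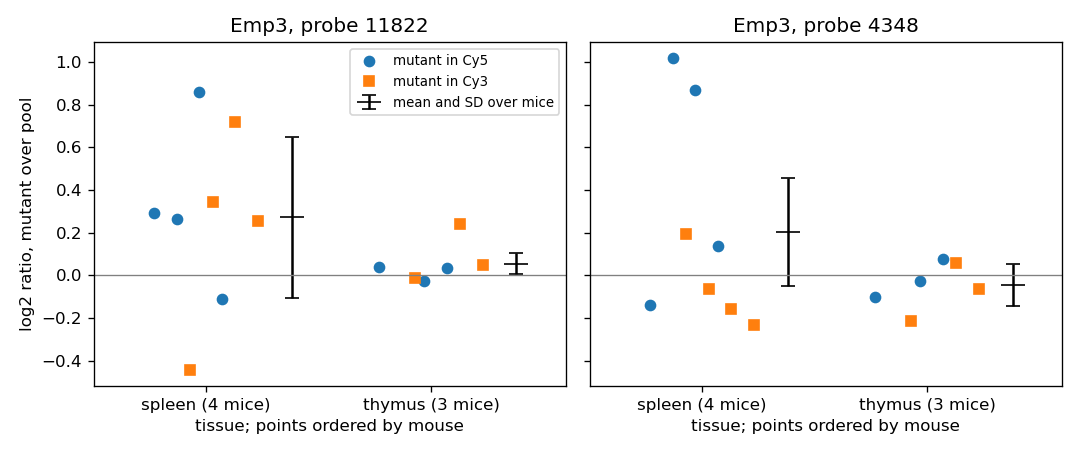
Log2 ratio of mutant over wild-type pool (y axis) for the 2 probes annotated to Emp3 in spleen and thymus (x axis), 1 point per array, ordered by mouse, with circles for the mutant RNA in Cy5 and squares for Cy3. Black bars are the mean and SD over mice; the spleen means are 0.27 and 0.20, with SDs of 0.38 and 0.25 that reach below 0.

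In spleen, the comparison of mutant mice with the pool asked which transcripts the mutation leaves at another level. With the ratio read as mutant over pool, the largest increases among probes with 1 gene symbol, past the threshold and with the same sign in all mice were at those annotated to Selenop, the plasma selenium transport protein, at a log2 ratio of 1.38 ± 0.14 (SD, n = 4), or 2.60-fold, and to Arpc5l, a subunit of the Arp2/3 actin complex, at 1.33 ± 0.14 (SD, n = 4), or 2.51-fold. Gzmc, a granzyme of cytotoxic lymphocytes, was higher by 1.32 ± 0.60 (SD, n = 3), the glutathione transferase Gsto1 by 1.31 ± 0.47 (SD, n = 4) and Ifnar2, a chain of the type I interferon receptor, by 1.07 ± 0.21 (SD, n = 4). The other higher probes under the naming rule were annotated to Abhd17a, Faf2, Fndc11, Gins3, Mmachc, Nagk and the troponin gene Tnnc2, with log2 ratios from 1.01 to 1.15. The largest decreases were at probes annotated to Fndc10, at -2.17 ± 0.67 (SD, n = 4), to Taf10, a subunit of the general transcription factor TFIID, at -2.07 ± 0.89 (SD, n = 4), and to the signalling ligand Wnt7a, at -1.96 ± 0.68 (SD, n = 4). Gata2, a transcription factor of blood progenitors, was at -1.32 ± 0.26 (SD, n = 4), and Atp2a2, the calcium pump of the endoplasmic reticulum, at -1.26 ± 0.59 (SD, n = 4). D17H6S56E-5, Slc25a44, Pan2, Ufd1, Glud1 (glutamate dehydrogenase), Mtfr1 and Fjx1 made up the 12 lower probes, with log2 ratios from -1.67 to -1.15. Pan2 was at -2.90 in mouse 2, -0.86 in mouse 3 and -0.64 in mouse 4. Ufd1 was at -0.64 in mouse 1, -2.64 in mouse 2 and -1.08 in mouse 3. Neither could be tested without mouse 2. All 24 probes had 1 direction in every mouse measured, and their adjusted p in limma ran from 0.000173 to 0.0228. In the fit of spleen alone, 3 of them missed the threshold: Gins3 (adjusted p = 0.0644), Pan2 (0.0763) and Ufd1 (0.0519). With the variance of the pool added, these and Fndc11 and Mmachc missed it, and the same 5 missed it in the 1.2-fold test. With the running median over neighbouring IDs removed, Fjx1 (-0.50, adjusted p = 0.179), Ufd1 (-0.945, 0.0776) and Fndc11 (0.79, 0.0544) missed it. Without mouse 4, Gins3 (adjusted p = 0.0648) and Slc25a44 (0.0507) missed it. Without mouse 3, Gins3 was at 0.595 and Fndc11 at 0.68.

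Over all probes, 7577 of 20127 tested in spleen passed an adjusted p of 0.05 in limma, 4363 of them higher and 3214 lower in the mutants (57.6% higher), and their median absolute log2 ratio was 0.35. The count passing a 1.2-fold test was 1576, of which 512 were higher and 1064 lower, and 105 of the probes past the threshold exceeded a log2 ratio of 1 in size, 30 higher and 75 lower. With each tissue fitted alone the count was 5086, and without mouse 4 it was 4207. Under the other reading of the dye exchange it was 12. Fitting both tissues together lends spleen the smaller spread of thymus (median SD between mice 0.158 in spleen and 0.086 in thymus): on simulated spleen values, 21.6% of the calls were false in the joint fit and 4.9% in the fit of spleen alone. The simulation changed only 100 probes at each size, with independent noise and no shared pool. Its shares of false calls therefore do not carry over to the 7577 calls. The wild-type pool was 1 control sample on every array of its tissue, so the test against 0 leaves out the spread of the controls, which no array measured. With the variance of a pool of 4 mice added, assumed to vary like the mutants, the count was 3943. It was 1689 when spleen was also fitted alone. The excess of higher probes was smaller or absent under some alternatives: 3732 were higher and 3580 lower with array medians set to 0 (51.0% higher), 1972 higher and 1971 lower with the pool's variance added, and 3006 higher and 3165 lower with the running median removed.

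**Figure D2:**
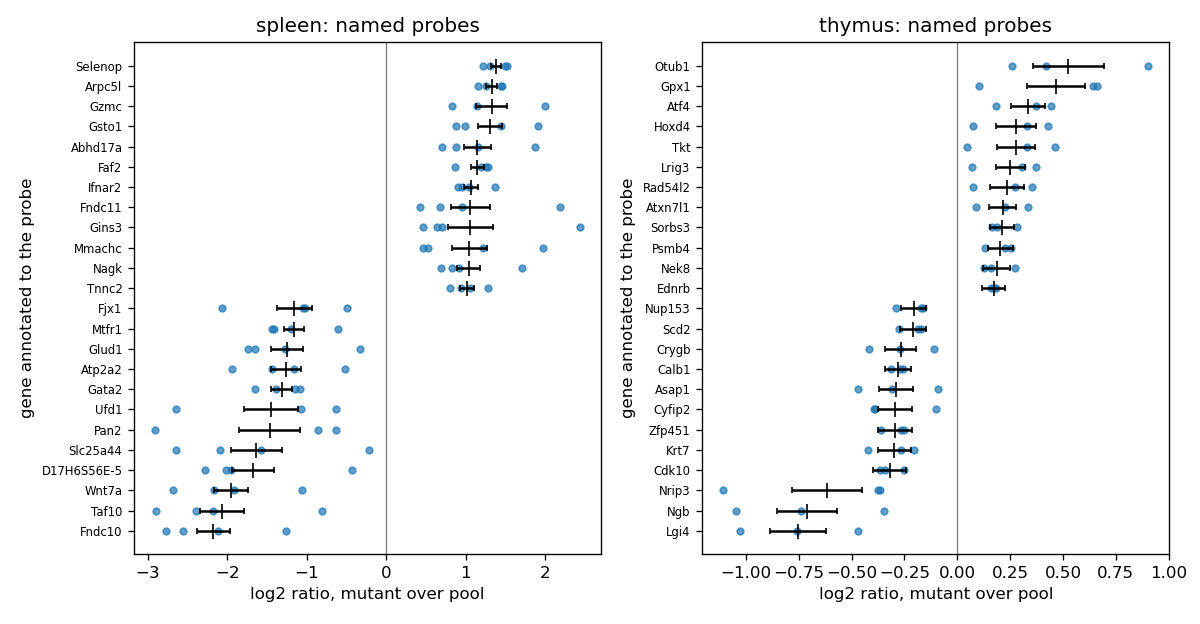
Log2 ratio of mutant over wild-type pool (x axis) for the named probes of spleen (left) and thymus (right), 1 row per probe with its annotated gene (y axis). Points are mice and black bars the mean and its standard error in limma; the 24 spleen probes passed the threshold, with means from -2.17 to 1.38, and the 24 thymus probes, from -0.75 to 0.53, did not.

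Grouped by the 33 gene lists, no list passed the threshold in spleen. Over all gene means, 3379 of 8836 passed, 1883 higher and 1496 lower, which is the background for the counts of list members. The apoptosis list came nearest: 12 of its 25 tested genes were lower and 1 higher, 13 passed when adjusted over the list alone, and the median log2 ratio was -0.27 (camera, adjusted p = 0.0587; adjusted p = 0.89 with an estimated correlation). With the running median over neighbouring IDs removed, the median was -0.02 and the adjusted p 0.945. Its members with the smallest p were Birc3, an inhibitor of apoptosis, at -0.97 ± 0.28 (SD, n = 4), and the initiator caspase Casp9 at -0.76 ± 0.23 (SD, n = 4). Of 34 striated muscle genes, 11 were lower and 5 higher, among them myoglobin (Mb, -0.52 ± 0.04, SD, n = 4) and desmin (Des, -0.60 ± 0.11, SD, n = 4), with an adjusted p of 0.478 for the list. Of 25 macrophage genes, 7 were lower and 4 higher, with the complement gene C1qb at -0.42 ± 0.05 (SD, n = 4) and the adaptor Tyrobp at -0.52 ± 0.11 (SD, n = 4). Of 22 genes for inflammation and cytokines, 6 were lower, such as Il18 (-0.67 ± 0.14, SD, n = 4) and Tgfb1 (-0.53 ± 0.14, SD, n = 4), and 4 higher. Of 33 genes for connective tissue and matrix, 5 were lower, with thrombospondin 1 (Thbs1) at -0.94 ± 0.25 (SD, n = 4) and the laminin chain Lamb1 at -0.77 ± 0.20 (SD, n = 4), and 3 higher. With the running median removed, Lamb1 was at -0.20 and missed the threshold (adjusted p = 0.0629). Of 16 glucocorticoid response genes, 3 were higher and none lower, with Lcn2 at 0.45 ± 0.05 (SD, n = 4) and the clock gene Per1 at 0.34 ± 0.07 (SD, n = 4). The macrophage, inflammation, matrix and glucocorticoid lists had adjusted p of 0.819 or 0.963 in camera. Among the cell type lists, 1 of 14 B cell genes was higher and none lower, 2 of 16 T cell genes were higher and 4 lower, and 9 of 26 erythroid genes were higher and 5 lower, each with an adjusted p of 0.963 for its list. Of 61 ribosomal protein genes 10 were higher and 8 lower, and of 59 cell cycle genes 14 were higher and 10 lower.

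The gene names were compared with the values themselves. Across 4431 pairs of probes annotated to 1 gene and lying more than 400 IDs apart, the rank correlation of the spleen log2 ratio was 0.000, inside the range of -0.030 to 0.031 that holds 95% of shuffled pairs. Where both probes of a pair passed the threshold, 324 of 621 pairs had the same direction (52.2%, 95% exact binomial interval 48.2% to 56.2%), and chance gives 51.1%. The 621 pairs came from 486 genes and are not all independent, so the interval is narrower than it should be. The named genes behaved likewise. Of 20 other probes of 14 named spleen genes, 2 passed the threshold in the direction of the named probe, 1 each for Gsto1 (log2 ratio 0.50) and Nagk (0.32), and 1 for Fjx1 passed in the opposite direction (0.32). The second Gata2 probe was at 0.00 and the second Taf10 probe at 0.04, while the second Wnt7a probe was at -0.66, with an adjusted p of 0.0894. Probes next to each other in ID order were more alike than probes of 1 gene, with a rank correlation of 0.169 for the spleen log2 ratio and 0.351 for the dye effect. The rank correlation between probes of 1 gene was 0.039 for the dye effect, just above its shuffled range, -0.033 for the thymus log2 ratio, just below its shuffled range, and -0.008 for the spread over the thymus arrays.

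**Figure D3:**
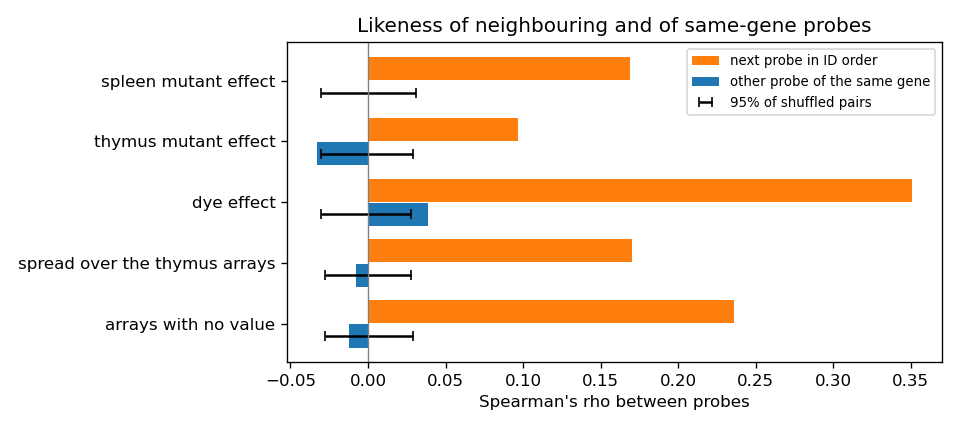
Spearman's rho (x axis) between neighbouring probes in ID order (orange) and between probes annotated to the same gene (blue) for the measures named on the y axis. Black bars span 95% of shuffled pairs; the same-gene value for the spleen effect is 0.000, against 0.169 for neighbouring probes.

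In thymus, no probe passed the threshold. Limma called 0 of 20130 probes in the fit with spleen, with 170 probes at an unadjusted p under 0.05 where 1006.5 would be expected by chance, and 0 when thymus was fitted alone, with 725 probes under 0.05. The joint fit gives thymus part of the larger spread of spleen (median SD between mice 0.086 in thymus and 0.158 in spleen). Its thymus test is therefore a strict one. No changed thymus probes were simulated, so the power behind the 0 calls was not measured. The standard deviation of the log2 ratio over probes was 0.08 for the thymus means and 0.31 for the spleen means. The probes with the smallest p that had 1 direction in all 3 mice are named as having missed the threshold, each with an adjusted p of 1. Lgi4, a secreted glial protein, was at -0.75 ± 0.28 (SD, n = 3), the globin Ngb at -0.71 ± 0.35 (SD, n = 3) and Calb1, a calcium-binding protein, at -0.28 ± 0.03 (SD, n = 3). Cdk10, Nrip3, Cyfip2, Crygb, Asap1, Zfp451, the keratin gene Krt7, Scd2 and Nup153 lay between -0.62 and -0.21. On the other side, Atf4, a transcription factor of the amino acid response, was at 0.33 ± 0.14 (SD, n = 3), the glutathione peroxidase Gpx1 at 0.47 ± 0.32 (SD, n = 3) and Otub1 at 0.53 ± 0.34 (SD, n = 3). Sorbs3, Lrig3, the proteasome gene Psmb4, Atxn7l1, Ednrb, Tkt, Rad54l2, Hoxd4 and Nek8 lay between 0.17 and 0.28.

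One of the 33 gene lists passed in thymus. The apoptosis genes were lower than the other genes (camera, adjusted p = 0.0368; adjusted p = 0.875 with an estimated correlation), with a median log2 ratio of -0.05 and 21 of 25 genes below 0, although no single gene of the list passed, over all genes or adjusted over the list alone. Bak1 (-0.14 ± 0.06, SD, n = 3), Aifm1 (-0.16 ± 0.22, SD, n = 3), Bid (-0.09 ± 0.06, SD, n = 3) and Birc2 (-0.07 ± 0.04, SD, n = 3) had the smallest p. Of the 46 probes of this list, 21 lay within 49 IDs of another member, or 45.7%, against a median of 19.6% for random probes. The call in camera ended with the running median over neighbouring IDs removed (adjusted p = 0.719), with array medians set to 0 (0.0533), under the other reading of the dye exchange (0.558, with the list higher), and without mouse 3 (0.313) or mouse 4 (0.813). With the running median removed, the list's median log2 ratio was still -0.035. The T cell list had a median log2 ratio of 0.00 in thymus and the cortical thymocyte list one of 0.03, both with an adjusted p of 0.878.

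The difference between the tissues was tested in the same fit. Of 19948 probes, 2692 differed in their log2 ratio between spleen and thymus, 1125 with a higher and 1567 with a lower value in spleen (41.8% higher). With the variance of the pool added the count was 187, of which 36 were higher and 151 lower (19.3% higher), and with the 1.2-fold test it was 4. Under the other reading of the dye exchange it was 0. The probes with the smallest p were annotated to Usp25, a deubiquitinating enzyme (spleen minus thymus -1.07 ± 0.08, SE), Selenop (1.33 ± 0.10, SE), Arpc5l (1.197 ± 0.10, SE), Zbtb5 (-0.78 ± 0.07, SE), Tbl2 (0.77 ± 0.07, SE), Zfand3 (-0.89 ± 0.09, SE), Itsn1, a scaffold of endocytosis (-0.78 ± 0.08, SE), and the splicing factor Srsf10 (-0.80 ± 0.08, SE), each with an adjusted p of 0.0053 in limma. On gene means, Tbl2 (0.19, adjusted p = 0.127), Itsn1 (-0.24, 0.0715) and Zfand3 (-0.71, 0.137) missed the threshold, and in the 1.2-fold test these, Zbtb5 and Srsf10 missed it at an adjusted p of 0.060. Of the 23 probes named for spleen that could be tested in both tissues, 17 differed between them, against 13.5% of all probes. They were chosen for large spleen ratios in the same fit, which favours a high share, so this count is no separate support. The same mice gave both tissues, and with the mouse as a block, which leaves 3 complete pairs, 0 probes passed and 4435 had an unadjusted p under 0.05. The differences kept their size under the block, at 1.28 for Selenop, 1.155 for Arpc5l and -1.04 for Usp25, and each of the 8 named probes had an adjusted p of 0.0564. Without mouse 3 the count was 3 and without mouse 4 it was 0. No gene list passed the threshold for the difference between the tissues (smallest adjusted p 0.366 in camera, for the apoptosis list).

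Across 19948 probes, which are not independent replicates, the mean effects of the 2 tissues correlated at r = 0.276 (Spearman's rho = 0.290). Arrays of opposite mutant dye gave -0.147 and -0.176 between the tissues, but there the dye effect enters with opposite signs. These values therefore do not settle the sign of the relation. The means cancel the dye effect only where it is equal on both arrays of a pair, which was not tested. A remainder shared by the tissues could add to the r of 0.276. Of 7545 probes called in spleen and tested in thymus, 5219 (69.2%) had the same sign in thymus, Lgi4 and Ngb among them, at -0.92 and -0.91 in spleen. The share over all probes was not counted, so whether 69.2% is particular to the called probes is unknown. Between mice, the spleen values correlated at 0.411 to 0.70 and the thymus values at -0.037 to 0.136. The mice of a tissue were measured against 1 pool, so its deviation enters each of them. In spleen, simulated unchanged mice against a pool of 4 correlated at 0.20 with a covariance of 0.0169, against a mean r of 0.531 and a covariance of 0.0749 in spleen. In thymus the simulated mean was 0.192, against an observed mean of 0.034. The pool was not split, so its part in these values is unknown. Exchanging the dyes showed a dye effect at 1296 of 20052 probes (limma, adjusted over all probes). The dye effect correlated at 0.531 between the tissues, and its standard deviation over probes was 0.26 in spleen and 0.21 in thymus, in thymus larger than that of the mutant effect, 0.08.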

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

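The tests of the ratio's sign and of the gene names were chosen after their results had been seen; the tests with the pool's variance and the running median were written down before they were run, on alternatives chosen after seeing the data.

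Among 52 groups of 4 spleen mice or 8 arrays, 5 had 1 value far from the others, where chance gives about 1 in 20. Mouse 3 stood apart for the Gins3 probe at a log2 ratio of 2.44, with the other mice between 0.46 and 0.69, and for an Emp2 probe at -0.25, with the others between 0.11 and 0.17. Mouse 1 stood apart for Birc3 at -0.55, with the others from -1.14 to -1.09, and for Lamb1 at -0.46, with the others from -0.90 to -0.84. The thymus array of mouse 1 with the mutant in Cy5 had a standard deviation over probes of 0.43, against 0.23 to 0.32 on the other thymus arrays.

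The mutant effect differed between spleen and thymus at 2692 probes. Of all 35 ways to divide the 7 mouse and tissue values into 4 and 3, 1 gave as many, the real one, and the highest of the others gave 426. These divisions ignore that the same animals gave both tissues. The division with 426 set spleen mice 2, 3 and 4 against the rest, so it also parts mostly tissues. Of the 8 divisions that part the tissues of mice 1, 3 and 4, the other 7 gave 0, and they differ from the real one in mixing tissues within a group; 8 divisions are too few for a share under 0.05. With the mouse as a block 0 probes passed, at differences of about the same size. Named probes with a higher value in spleen, as spleen minus thymus on the log2 scale, were Selenop (1.33), Arpc5l (1.197), Gsto1 (1.17), Gzmc (1.17), Abhd17a (1.11), Faf2 (1.08), Nagk (1.04), Ifnar2 (1.03), Tnnc2 (0.94), Tbl2 (0.77) and Nup153 (0.40). Those with a lower value in spleen were Taf10 (-2.09), Fndc10 (-2.05), Wnt7a (-1.95), D17H6S56E-5 (-1.52), Gata2 (-1.44), Glud1 (-1.23), Atp2a2 (-1.16), Usp25 (-1.07), Zfand3 (-0.89), Mtfr1 (-0.88), Srsf10 (-0.80), Zbtb5 (-0.78) and Itsn1 (-0.78). Smaller negative differences were found for Tkt (-0.68), Rad54l2 (-0.64), Zfp451 (-0.51), Cyfip2 (-0.48), Psmb4 (-0.39), Scd2 (-0.33) and Calb1 (-0.32).

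The first pattern is the number of probes called in spleen, 7577. A ratio left unturned on the Cy3 arrays is argued against by the placeholder, whose sign followed the mutant dye on 16 of 16 arrays. This holds only if the spots without signal lacked the same dye on every array, which was not tested. Place in the ID order is argued against as the whole cause, since 6171 probes passed with the running median removed. With the variance of a pool of 4 mice added 3943 probes passed. In the main fit, whose count in the data was 7577, 20 simulated sets of unchanged mice against such a pool gave at most 498. The simulation drew independent noise for each probe and took the pool's spread from the mutant mice. In thymus its mean correlation between mice was 0.192, against 0.034 observed. It therefore does not exclude the pool as a source of the calls. The criterion written before the test with the pool's variance would have excluded the spread of the wild-type mice at 3943. It was set aside after the count was seen. The reasons were that 1689 passed when spleen was also fitted alone and that no array shows how wild-type mice vary. For the calls lost under that variance this spread and the mutation cannot be told apart, and a deviation of the 1 pool from other wild-type mice and an effect of the mutation stay open and untested.

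The second pattern is that probes annotated to 1 gene did not share their spleen effect. Noise between mice is argued against, because the spleen effect correlated between mice at a median of 0.512. The mice share 1 pool and the same spots, so values that repeat between mice need not follow the transcript. An effect of place in the ID order was not weighed for this pattern. Names displaced by a fixed shift or by a plate's well order are argued against by 27130 other orders, of which the highest rank correlation between probes of 1 gene was 0.074 in any of 3 measures. A candidate explanation is that many names do not belong to the rows they stand in, or that many spots do not hold the named clone: the spread over the thymus arrays had a rank correlation of -0.008 between probes of 1 gene, inside its shuffled range, although whether this spread follows the transcript was not tested. Of 9 measures the dye effect lay just above its shuffled range, at 0.039, and the thymus effect just below, at -0.033, which decides nothing, and no biological explanation was tested.

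The third pattern is the lower apoptosis list, past the threshold in thymus and near it in spleen. With the running median over neighbouring IDs removed, its p in thymus was 0.0611 before adjustment over lists, against 0.00112 without, while its median log2 ratio went from -0.05 (quartiles -0.10 and -0.01) to -0.04 (quartiles -0.10 and 0.00); in spleen the median went from -0.27 to -0.02. Probes beside the clustered members that belong to other genes or to none had medians of -0.14 in spleen and -0.02 in thymus, against 0.04 and 0.01 over all probes. The criterion written before this test would have named place in the ID order as the cause at 0.0611. It was set aside after the value was seen, because the thymus median moved little and the correction also removes part of any shift that neighbouring members share. For thymus, place in the ID order and an effect on the genes named therefore cannot be told apart. Chance stays open too: the call ended with an estimated correlation (camera, adjusted p = 0.875) and without mouse 3 (0.313) or mouse 4 (0.813). Names that do not belong to their rows also stay open. In spleen the list had not passed, and no explanation was weighed there.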

How the results depend on the processing

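The placeholders kept, the mirrored pair used, the running median and the pool's variance were tests chosen after the results had been seen; the other alternatives were set before the data were examined.

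The spleen count of 7577 probes was 1576 with the 1.2-fold test and 3379 on gene means, where a stricter test and fewer units tested lower it by construction. It was 3943 with the pool's variance added and 4207 to 7244 with 1 mouse left out, lowest without mouse 4, and 4257 in the fit with the mouse as a block. The fit of all arrays with the mouse as a random block gave 8022. Its correlation within a mouse, estimated across both tissues, was -0.073. The 2 arrays of a mouse therefore counted nearly as separate replicates, and this count is no measure of stability. Under the other alternatives run the spleen count stayed within 1.5 times, apart from the other reading of the dye exchange. In that reading the sign on the Cy3 arrays is turned and 12 probes passed. That reading subtracts the arrays of a pair, so it measures the dye effect if the first reading is right.

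Thymus had 0 probes past the threshold in limma under every alternative run, with 4 to 1616 at an unadjusted p under 0.05. The difference of 2692 probes between the tissues was 4 with the 1.2-fold test, 1112 on gene means, 187 with the pool's variance added, 4484 with thymus mouse 2 as deposited and 0 with the other reading. With the mouse as a block, which leaves 3 pairs, it was 0. Leaving out 1 mouse gave 0 to 2055, with 3 without mouse 3, 0 without mouse 4 and 2055 without mouse 1. The cause was not tested.

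No list passed in spleen, and leaving out 1 mouse gave 0 to 1, the 1 being the apoptosis list without mouse 1 or mouse 4. In thymus 1 list passed, and 0 did with an estimated correlation, array medians set to 0, the other reading or the running median removed; leaving out 1 mouse gave 0 to 1, with 0 without mouse 3 or mouse 4. The cause was not tested.

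The correlation between the tissues of 0.276 was -0.147 and -0.176 between arrays of opposite dyes, where the dye effect enters with opposite signs. It was 0.138 between spleen of mice 3 and 4 and thymus of mouse 1, and 0.197 to 0.277 with 1 mouse left out. Emp3 probe 4348 was at -0.064 in spleen with the mutant in Cy3 alone, and in thymus at -0.075 to 0.012 with 1 mouse left out, above 0 without mouse 1. The dye effect was found at 1225 probes with array medians set to 0, against 1296.

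Thymus had 0 calls under every alternative, so no thymus value changed its side of the threshold. Some alternatives, such as robust moderation, leave a log2 ratio as it is, and adding thymus mouse 2 leaves spleen ratios as they are. The share of kept values is therefore no measure of robustness. For the named genes, 1170 of 1290 values under alternatives kept their direction and side of the threshold, 80 kept the direction alone and 40 reversed, 35 of them under the other reading. In spleen these were Arpc5l (-0.19), Gsto1 (-0.28), Faf2 (-0.15), Fndc11 (-0.85), Nagk (-0.20), Pan2 (0.31), Atp2a2 (0.010), Mtfr1 (0.026) and Fjx1 (0.73), and as gene means Birc3 (0.082), Casp9 (0.10), Mb (0.001) and Tgfb1 (0.048). In thymus they were Sorbs3 (-0.11), Lrig3 (-0.20), Ednrb (-0.027), Tkt (-0.073), Rad54l2 (-0.037), Hoxd4 (-0.13), Nek8 (-0.089), Otub1 (-0.025), Lgi4 (0.046), Ngb (0.17), Calb1 (0.047), Cdk10 (0.19), Cyfip2 (0.085), Crygb (0.090), Zfp451 (0.083), Krt7 (0.18) and Scd2 (0.018), and as gene means Bak1 (0.27), Bid (0.14) and Birc2 (0.25). For spleen minus thymus they were Selenop (-0.054) and Arpc5l (-0.097). Tkt was at -0.049 in thymus with mouse 2 added under the sign of its Cy5 array. With 1 mouse left out, the Emp2 probe 18713 ranged from -0.005 (without mouse 4) to 0.135 in spleen and from -0.049 (without mouse 1) to 0.143 in thymus, the Emp2 probe 19447 from -0.16 to 0.051 (without mouse 1) in thymus, and Pmp22 from -0.038 to 0.011 (without mouse 4) in thymus. The cause of these reversals was not tested. Intensities were not used here, so what signal over background limits is unknown.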

Other observations

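The test of the mirrored thymus arrays and the genes and lists singled out here were chosen after the values had been seen; the comparison of tissues from different mice was planned.

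The correlation of the mutant effect between tissues was also positive where no mutant animal gave both tissues, though whether the pools of the tissues shared donors was not tested: spleen of mice 1 and 2 against thymus of mice 3 and 4 gave r = 0.272 across probes, and spleen of mice 3 and 4 against thymus of mouse 1 gave 0.138. Pairs of tissues from 1 mouse correlated at 0.046 to 0.164, and the 9 pairs from different mice at 0.091 to 0.186. Whether a remainder of the dye effect in the means adds to these correlations was not tested. Among the thymus probes named as having missed the threshold, 10 of the 12 lower ones and 7 of the 11 higher ones measured in both tissues had the same sign in spleen. No share over all probes was counted beside these. Lgi4 and Ngb, the lowest of the probes named for thymus, were also lower in spleen, at -0.92 and -0.91. Their difference between the tissues did not pass the threshold (limma, adjusted p = 0.574 and 0.530).

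In spleen, genes of unrelated cell types passed the threshold in both directions. Over all genes, 3379 of 8836 passed there, 1883 higher and 1496 lower, so calls in both directions are not particular to these lists. Of 18 genes for class II antigen presentation and dendritic cells 7 were higher and 1 lower, of 8 NK and cytotoxic cell genes 4 were higher and 3 lower, and of 17 granulocyte genes 2 were higher and 3 lower. Of 18 exocrine pancreas genes, which mark a neighbouring organ, 5 were higher and 3 lower, and of 24 adipocyte genes 5 were higher and 2 lower. Of 26 interferon response genes 6 were higher and 6 lower. Each of these lists had an adjusted p of 0.963 in camera.

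The mirrored thymus arrays of mouse 2 were compared with what a pair of separate hybridisations with a strong dye effect would give. Their sum lay within 0.01 of its median for 83.8% of the probes, against 1.33% to 6.08% in the other 7 pairs, which argues against separate hybridisations. How these values arose was not tested.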
